A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

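RNA was sequenced from the left ventricle of adult rabbits (Oryctolagus cuniculus) after a sham operation, in which a thread was passed around a coronary artery without closing the vessel. Hearts were taken 3 weeks later and rinsed free of blood, per the labels' protocols. The series holds 6 libraries, and the labels put all of them in 1 group. There is no untreated, infarcted or otherwise different group among the samples used here. The titles carry 2 number prefixes, 13872 and 14285, with 3 libraries each. The labels name 2 RNA extraction kits without saying which library had which, and they do not say what a prefix stands for. Libraries are called 1 to 3 (prefix 13872) and 4 to 6 (prefix 14285), in accession order. The labels speak of animals but do not tie each library to one, so p-values measure the spread between these libraries, part of which may be technical.

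Ribosomal RNA was depleted from total RNA and strand-specific libraries were sequenced as read pairs, per the labels' protocols. The deposited files hold raw counts of fragments per gene, in the layout of STAR's gene count table. STAR, DESeq2 and the genome build OryCun2.0 are named in the submitters' processing notes. Versions, the annotation release and alignment settings are not given in the sources used here. Each table gives counts without regard to strand, and counts for each strand separately. Column 4 held more gene counts than column 3 in every library, and it is the count used here. Column 3, called the other strand, held 1.82% ± 0.43 (SD, n = 6) of the counts on both. Each table opens with 4 rows that name no gene, and these stayed out of library sizes and tests. Of all fragments, they took 6.50% ± 1.87 (unmapped), 7.49% ± 0.73 (several places), 46.7% ± 1.3 (no gene feature) and 0.069% ± 0.053 (ambiguous gene), as mean ± SD over 6 libraries.

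The deposited count tables identify genes by Ensembl rabbit IDs and do not pair them with names. The reference table provided lists 38822 genes of another assembly, mOryCun1.1, and none of its rows carries an Ensembl ID, so 0 of the 23669 IDs matched a symbol. No name was taken from elsewhere. The 29 gene lists, 48 gene pairs and 6 correlations between named genes that had been fixed before the data were examined were therefore not run. The rule for named genes asked for symbols. In its place the text names up to 4 IDs by mean level, the 2 IDs with the largest fall between prefixes under the rule's other criteria, and IDs from the 15 with the largest spread. ENSOCUG00000026762, ENSOCUG00000029097, ENSOCUG00000026619, ENSOCUG00000013591 and ENSOCUG00000021750 fall outside this rule and were chosen after their values were seen. Exon lengths and biotypes were not used here either, so levels are not scaled for length. A long gene collects more counts than a short one at equal abundance.

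Levels are CPM, an ID's share of all counts on genes in its library. The prefix comparison used edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr with the prefix as group, and the quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are 14285 over 13872. Standard errors were taken as the absolute log2 fold change over the square root of the F statistic. Single values per library were compared between prefixes with an exact two-sided permutation test (scipy 1.17.1), whose smallest p for 3 against 3 is 0.1. The spread is the SD over 6 libraries of log2 TMM-normalized CPM (prior count 2) of IDs with a mean of 5 CPM or more. Counting noise alone was estimated from Poisson counts drawn at each ID's mean share.

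In simulated counts with 200 IDs changed, of which 198 passed the filter among 11807 fitted, the prefix test recovered 58.2% of those changed 2-fold and 96.0% of those changed 4-fold, with 10 calls on unchanged IDs. These counts were drawn independently, with the spread that edgeR had fitted to each ID. The shares recovered may therefore not hold for the real libraries. In a simulation of 9277 IDs with a true SD of 0.5, the root mean square of the recovered SDs was 0.509. The median SD given in the results was not checked in this way. Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no low-count filter, unstranded counts, a test against a 1.5-fold change, each library left out, other expression minimums, CPM with no TMM, and the SD within prefix. Robust edgeR, thinned counts and the removal of a run of 37 IDs were added after seeing the data.

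Depth ranged from 25427072 to 34882484 fragments, and from 9829581 to 12514152 counts on genes. A count of 3, the limit that a count of 0 allows, was 0.240 to 0.305 CPM. Wilson 95% intervals of the fragment shares of single libraries spanned at most 0.039 percentage points. Intervals and floors cover counting error only, since the tables carry no molecular identifiers. A chi-square test of counts between libraries gave at least 17.8 per degree of freedom in each pair, so no library was a second deposit of another.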

Results

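The transcriptome of the left ventricle, the heart's main pumping chamber, was measured in 6 libraries from sham-operated adult rabbits. All libraries belong to 1 group, so the data give the levels of transcripts in this tissue and their spread between libraries. The division used here is the number prefix of the titles, with 3 libraries under 13872 and 3 under 14285. The titles also carry a library number, which was not used. Because the tables carry Ensembl IDs without names, no transcript is described here by its function.

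On average 39.3% ± 2.9 (SD, n = 6) of fragments were counted on an annotated gene. A larger share, 46.7% ± 1.3, aligned to 1 place but was counted on no gene in the strand column used. This share includes fragments on the other strand of annotated genes, so not all of it lay outside the annotated features. Fragments counted on the other strand were few, with a mean of 209387 per library against a mean of 28791068 fragments in all. The libraries under 14285 left 4.87% ± 0.25 (SD, n = 3) of fragments unmapped, against 8.14% ± 0.84 (SD, n = 3) under 13872, with no overlap. They also placed more fragments on genes, 41.5% ± 1.7 against 37.04% ± 1.73, again without overlap. Each difference had p = 0.1 in the exact two-sided permutation test, the smallest that 3 against 3 allows, and an adjusted p of 0.36 over 18 measures per library. Shares of multiply mapped fragments overlapped between the prefixes, at 7.42% ± 0.64 and 7.56% ± 0.95 (exact permutation p = 0.9).

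**Figure D1:**
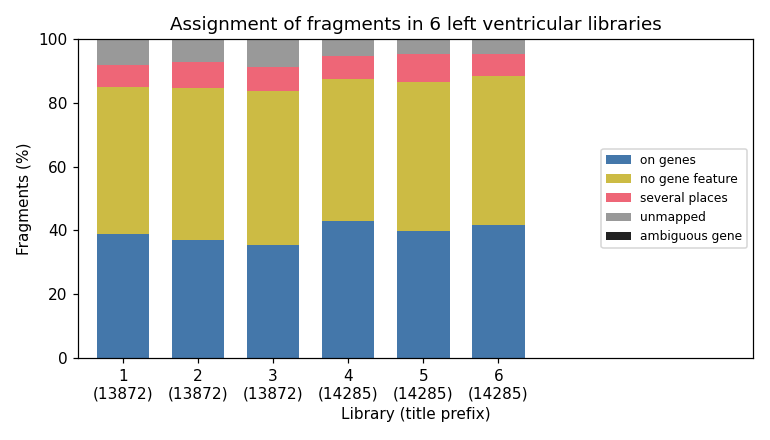
Stacked bars give the percentage of all fragments in each assignment class for the 6 libraries, with the title prefix under each library number. The unmapped share is 7.27% to 8.94% in libraries 1 to 3 and 4.71% to 5.16% in libraries 4 to 6.

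The transcriptome was dominated by few IDs. ENSOCUG00000016777 alone took 16.03% ± 1.46 (SD, n = 6) of all counts on genes, from 13.7% in library 1 to 18.2% in library 6. ENSOCUG00000029096 followed with 6.002% ± 1.711, ENSOCUG00000011037 with 5.75% ± 1.02 and ENSOCUG00000029084 with 2.46% ± 1.48. The 10 highest IDs of each library held 36.1% ± 2.0 of its counts, the 100 highest 51.2% ± 2.0 and the 1000 highest 73.6% ± 1.3. At the other end, 5088 of the 23669 IDs (21.5%) had no count in any library. A mean of 1 CPM or more was reached by 11773 IDs, of 100 CPM or more by 1274 and of 1000 CPM or more by 68. Each library under 13872 had a count on more IDs (16325 ± 302, SD, n = 3) than each under 14285 (15311 ± 114), while their totals on genes overlapped; the exact permutation p was again 0.1, with an adjusted p of 0.36.

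The title prefix was compared to see how far it structures the libraries, although the labels do not say what it stands for. Of 11945 IDs tested, 5 were lower under 14285 and 0 were higher at an adjusted p under 0.05 (edgeR quasi-likelihood test). None of the 5 had a mean over all 6 libraries of 100 CPM or more. ENSOCUG00000021631 fell the furthest, from 30.0 ± 4.9 CPM (SD, n = 3) under 13872 to 2.20 ± 0.31 under 14285. Its log2 fold change was -3.70 (SE 0.19, adjusted p = 0.000407, edgeR). ENSOCUG00000028503 fell from 107.0 ± 22.6 to 27.6 ± 7.2 CPM, a log2 fold change of -1.89 (SE 0.19, adjusted p = 0.0292, edgeR). The called IDs had a median absolute log2 change of 1.62, and in all 5 the libraries of the prefixes did not overlap.

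At an unadjusted p under 0.05 edgeR listed 2511 IDs, or 21.0% of those tested. Their median absolute log2 change was 0.49, and 90.4% of them lay under 1. In 26.2% of the tested IDs the prefixes did not overlap, where chance gives 10%. The number of calls depended on the tool. DESeq2 called 360 IDs lower and 148 higher under 14285, and the 5 edgeR calls were among them. With any 1 of the 6 libraries left out, edgeR called 1 or 2 IDs. ENSOCUG00000021631 kept its call each time. ENSOCUG00000028503 lost its call in 5 of the 6 fits and kept it only without library 5, where its log2 fold change was -2.09 (adjusted p = 0.0154, edgeR); over the 6 fits the change ranged from -2.09 to -1.76.

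**Figure D2:**
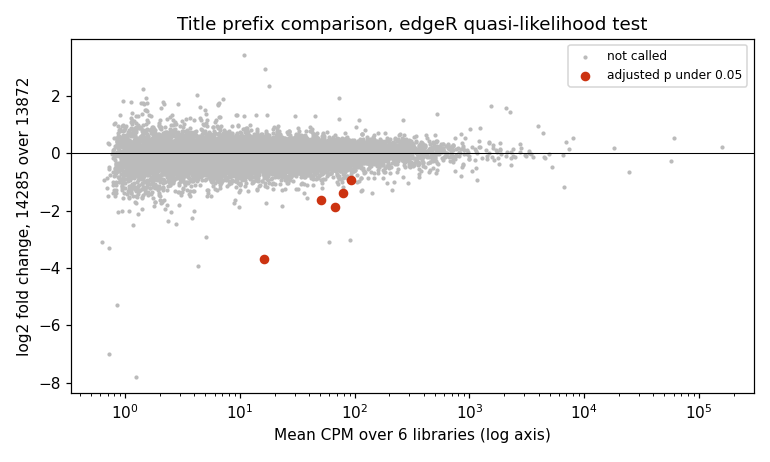
Each point is 1 of 11945 IDs, with its mean CPM over 6 libraries on a log axis and its log2 fold change of 14285 over 13872 (edgeR). The 5 called IDs lie below 0 and have means between 10 and 100 CPM.

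Between libraries, most IDs varied little. Among 9277 IDs with a mean of 5 CPM or more, the median SD of log2 CPM was 0.226, where counting noise alone gave 0.076. An SD under 0.25 was seen for 5369 IDs (57.9%), and 86 IDs (0.93%) had an SD of 1 or more. Across these IDs, Pearson's r between libraries ranged from 0.940 to 0.972 for the 6 pairs within a prefix and from 0.927 to 0.965 for the 9 pairs across prefixes. These correlations are across genes, which are not independent replicates. The mean r was higher within prefixes by 0.0099, and 2 of the 10 splits of the libraries, the real one included, gave a difference as large (exact permutation p = 0.2, one-sided). The other of these splits parts libraries 1, 4 and 6 from 2, 3 and 5, and its difference was larger. The IDs correlated include 17 of a run of consecutive IDs, described below, in which many IDs part the libraries in this same way. The run holds 11 of the 15 IDs with the largest SD. The correlations were not repeated without it. How far r and the comparison of splits reflect the run, and how far all IDs, was therefore not tested.

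**Figure D3:**
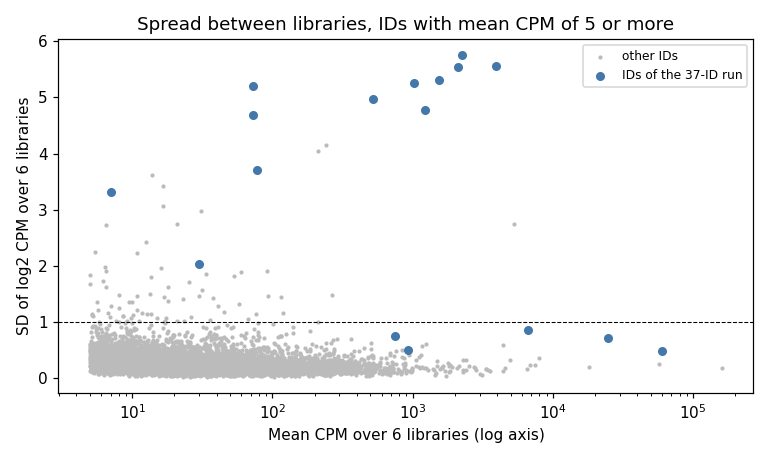
Each point is 1 of 9277 IDs, with its mean CPM on a log axis and the SD of its log2 CPM over 6 libraries; larger points mark the run of 37 consecutive IDs and the dashed line an SD of 1. The IDs with the largest SD belong to the run, with values up to 5.75.

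The largest spread was concentrated in 1 place of the tables. Of the 15 IDs with the largest SD, 11 lay in a run of 37 rows with consecutive IDs, from ENSOCUG00000029081 to ENSOCUG00000029117. This run also holds ENSOCUG00000029096 and ENSOCUG00000029084, named above for their abundance, and took 5.97% to 16.1% of counts on genes. Of its IDs, 17 had 100 or more counts in a library. In 6 of these the highest library exceeded the lowest by 1.97-fold to 23.3-fold. In the other 11, the range was 111-fold to 2757-fold, with any count under 3 raised to 3 in its own library. ENSOCUG00000029112 stood at 3694, 4263 and 5582 CPM in libraries 1, 4 and 6, and at 4.38, 2.02 and 3.46 CPM in libraries 2, 3 and 5. ENSOCUG00000029099 stood at 8092, 7400 and 8029 CPM in libraries 1, 4 and 6, and at 10.4, 5.91 and 6.08 CPM in the others. Both prefixes hold libraries at high and at low values, so this spread does not follow the prefix.

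**Figure D4:**
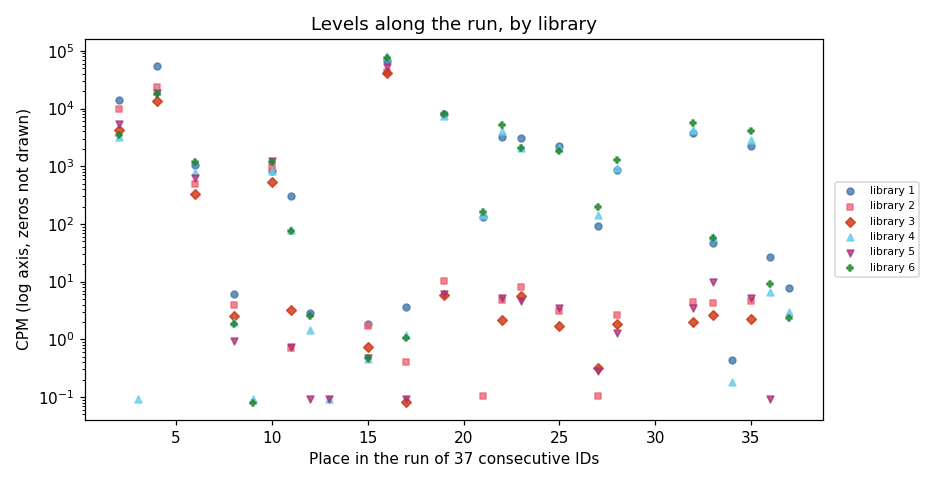
CPM on a log axis of each ID along the run of 37 consecutive IDs, with 1 symbol per library; zeros are not drawn. Libraries keep close at place 16 (ENSOCUG00000029096) and lie apart at most places from 19 on: at place 19 (ENSOCUG00000029099) libraries 1, 4 and 6 stand at 7400 to 8092 CPM and libraries 2, 3 and 5 at 5.91 to 10.4 CPM.

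Outside the run, ENSOCUG00000024282 was at 167 to 384 CPM in 5 libraries and at 0.081 CPM, from 1 count, in library 3. ENSOCUG00000025982 ranged from 1.28 to 622 CPM, and its neighbour in the next row, ENSOCUG00000026762, from 272 to 12344 CPM. In all, 21 IDs had 3 or fewer counts in a library and 100 or more in another. Of these 21, 7 were near absent in 1 library, 7 in 2 libraries, 6 in 3 and 1 in 4, and 3 lay in the run.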

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

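The tests of explanations in this part were chosen after the results were seen.

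Of 29 sets of 6 values tested for a library far from the others, 2 stood out, where chance gives about 1 in 20. The 1000 highest IDs held 71.1% of counts in library 3, the lowest of the 6 libraries. ENSOCUG00000029084 reached 54046 CPM in library 1, against 13474 to 23497 CPM in the other libraries. The other-strand counts of single IDs enter no comparison above. Among them, ENSOCUG00000029097 reached 119493 counts in library 4 (44.6% of that library's other-strand counts), with 13 counts on its own strand.

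By the SD of log2 CPM, the 9 IDs with the largest spread between libraries lie in the run of 37 IDs. In each of the 11 IDs with a range over 100-fold, the lowest libraries were 2, 3 and 5. Whether transcription changed on 1 strand only was not settled by the other strand. The stretch from the first to the last of these 11 IDs covers places 11 to 36 of the run. In it, 4 IDs had most of their counts on the other strand and 100 or more such counts in a library. Their range was 34.9-fold at the median (2.99-fold to 88.3-fold). ENSOCUG00000029097 stood at 3708 to 5391 counts in libraries 2, 3 and 5 and at 68532 to 119493 in the others. The other strand is relative to the annotated strand of each ID, which was not used here. The counts of these 4 IDs may therefore lie on the same strand of the genome as those of the 11 IDs. Other-strand counts of the 11 IDs themselves lie opposite to their own counts. ENSOCUG00000029112 had 6605, 7291 and 10004 other-strand counts in libraries 1, 4 and 6, next to 41508, 46619 and 69850 on its own strand. In libraries 2, 3 and 5 it had 10, 7 and 8. It is 1 of the 11 IDs and was picked after its values were seen. Whether such counts are reads assigned to the wrong strand was not tested. Reads assigned to a near-identical copy elsewhere stay open. In 6 of 6 libraries exactly 1 of ENSOCUG00000029099 and ENSOCUG00000026762, an ID far from the run, exceeded 1000 CPM. ENSOCUG00000026762 was chosen after its values were seen, so this count is no independent support. The 11 IDs took 0.933% to 1.194% of fragments in libraries 1, 4 and 6 and 0.001% in libraries 2, 3 and 5. ENSOCUG00000026762 and its neighbour ENSOCUG00000025982 together took less, 0.320% to 0.515%, in libraries 2, 3 and 5. Multiply mapped fragments made up 8.02%, 7.48% and 8.64% in libraries 2, 3 and 5 and 6.75%, 7.18% and 6.85% in libraries 1, 4 and 6. Fragments of an ambiguous gene parted the libraries in the same way. They made up 0.021%, 0.022% and 0.019% in libraries 2, 3 and 5 and 0.117%, 0.113% and 0.124% in libraries 1, 4 and 6. No sequence was used here to test identity. Animals that differ in sequence over this stretch could then send reads to different copies. The run has 37 IDs, as many as a vertebrate mitochondrial genome has genes, and a mitochondrial origin is a candidate for what the run is. It was not tested by position, since neither the tables nor the reference table place these IDs on a chromosome. The order of the counted IDs and their strands along the run was not compared with that genome. Such an origin would not by itself account for the difference of libraries 1, 4 and 6 from 2, 3 and 5.

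For the title prefix, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 5 IDs and the highest other split 17, so 2 of 10 splits called as many. That other split parts libraries 1, 4 and 6 from 2, 3 and 5, which points to the structure in the run: 13 of its 17 calls lie in the run, and 2 calls were made with the run left out. Under other fits no other split called as many as the real one: 508 against at most 30 with DESeq2, 36 against at most 14 with robust edgeR, and 5 against at most 2 without the run. By IDs at an unadjusted p under 0.05, the real split had 2511 and the highest other 690, so 1 of 10 splits, the real one, had as many. The totals of counts on genes overlapped between the prefixes, at 11138290 ± 1263016 under 13872 and 11378642 ± 991333 under 14285 (SD, n = 3 each), and thinning all libraries to the same total changed little, with 6 IDs called. What the prefix stands for stays open: a sequencing batch, the extraction kit and the animals cannot be told apart with these labels.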

How the results depend on the processing

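The prefix comparison kept 0 IDs higher and 5 lower with DESeq2 size factors and with the run of 37 IDs left out, and the 5 were the same IDs. Unstranded counts and thinned counts each gave 6 lower, the 5 included. Larger numbers came with DESeq2 (148 higher, 360 lower), with no low-count filter (8 higher, 71 lower) and with robust estimation of the spread (2 higher, 34 lower), each with the 5 among them. DESeq2 gave no adjusted p for 1166 IDs. A test against a 1.5-fold change left 1 ID lower, and leaving out 1 library at a time left 1 to 2; the cause was not tested beyond the fewer libraries. ENSOCUG00000028503 kept its direction throughout, but lost its call against a 1.5-fold change (adjusted p = 0.139) and in 5 of 6 fits with 1 library left out (adjusted p of 0.0154 to 0.199, log2 fold change of -2.09 to -1.76). The number of IDs with an SD of 1 or more was 247 at a minimum of 1 CPM and 38 at 20 CPM, which test more and fewer IDs. It stayed between 80 and 99 with 1 library left out. The median SD was 0.186 within prefixes. Without the run of 37 IDs, the 10 highest IDs held 31.6% of the remaining counts and the highest 17.9%, since the run holds 3 of the 10. Leaving out mitochondrial genes and non-coding biotypes, the gene list tests, the gene pairs and the correlations were not run, because no ID has a name or biotype here. No paired analysis was possible because the labels give 1 group.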

Other observations

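The prediction for adjacent rows was written before the test; the other values of this part were picked after they were seen.

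The hypothesis was tested that IDs in adjacent rows of the tables vary together between libraries. Over 4377 pairs of adjacent rows with a mean of 5 CPM or more, outside the run of 37 IDs, the median correlation over the 6 libraries was 0.215. Random pairings of the same IDs had a median near 0.002, and the highest of 1000 pairings reached 0.052. After centring on the prefix means the median was 0.117, against 0.041 for the highest pairing. At the median, IDs in adjacent rows thus varied together more than randomly paired IDs, as the prediction stated. Whether this holds for neighbours on the genome stays open, since the tables do not state that the rows follow it. Shared base composition, overlapping annotations and shared regulation were not tested, since no sequence or coordinates were used here.

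Some IDs near absent in 1 library stood close in the tables, and how often this happens by chance was not tested. ENSOCUG00000024282 in row 3328 and ENSOCUG00000026619 in row 3305 each had 1 count in library 3, against 2092 to 4107 and 147 to 443 counts in the other libraries. In all, 4 IDs were near absent in library 3 only, and the rest of them lay farther off, in rows 4709 and 4936. ENSOCUG00000013591 and ENSOCUG00000021750, in rows 7329 and 7330, had 1 and 0 counts in library 1, against 22 to 124 and 17 to 143 in the others. On the other strand, 393 IDs had 10 or more counts in each library and more there than on their own strand.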
